A study of Mus musculus with 6 samples.

How the data were processed

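Bulk RNA sequencing was carried out on the cerebral cortex of mouse embryos of the C57BL/6 strain at embryonic day 18, with 3 wild-type libraries and 3 libraries from embryos in which both copies of Csmd3 were disrupted. Per the labels' protocols, the embryos came from matings of heterozygous parents, RNA was extracted with TRIzol (a phenol and guanidine reagent), and libraries for Illumina sequencing were made from total RNA. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.4.4, HISAT2 2.0.5 (an aligner) and StringTie 1.3.4 (a transcript assembler and quantifier) and the genome build mm10, without saying which step each served. The program that wrote the gene counts, the annotation release and the handling of read strand are not given in the sources used here, and neither is the part of Csmd3 that was removed.

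The deposited table held whole-number gene counts, per the file headers, for 55401 gene rows in 6 columns. They were treated as estimated counts, because low values were not spread evenly: in wild-type library 1, 1298 genes had a deposited count of 4, against 492 with a count of 3 and 318 with a count of 5, and similar excesses stood at 8 and 12 in all 6 libraries. A single sequenced fragment therefore appears to add about 4 to a deposited count, so a value carries the counting precision of that value divided by 4. The deposited estimated counts were already whole and needed no rounding. Deposited totals ran from 54244288 to 68269607 counts per library, and 24460 to 25122 genes had a count above 0. The floor for a gene with no counts in the wild-type group was set at 3 fragments, or 12 deposited counts, over the 3 libraries together. Where the wild-type group held 1 to 3 fragments, the fold is given with an exact 95% binomial (Clopper-Pearson) interval on fragments. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

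Identifiers were matched to GENCODE release M21 on the same genome assembly as mm10. Of the 55401 rows, 55141 received a gene name, 54349 of them with an identical versioned identifier, and rows without a name held at most 0.0238% of the counts in any library. Coordinates are from that annotation, counted from 1.

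Groups were taken from the genotype stated in the labels. Genes were kept by filterByExpr, scaled by TMM, and compared by the quasi-likelihood F-test of edgeR 4.0.16 with robust dispersion in R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and every adjusted p for a gene comes from this test unless another is named. Fold changes are log2 values of knockout minus wild type. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic. CPM is the count scaled to library size by TMM, as mean ± SD over 3 libraries. Fitted fold changes of genes near 0 in a group, and the SE derived from them, depend on the small constant that edgeR adds to counts.

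Gene lists were tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The test is two-sided, compares a list with all other tested genes, and was adjusted over the 37 lists of at least 5 tested genes. Camera was repeated with a correlation estimated for each list. In that form it also tests with the few residual degrees of freedom of 6 libraries, not with those of all genes. It therefore has little power over 37 lists, and a call lost there is not evidence of correlated genes by itself. Fry was run as a rotation test of whether the genes of a list move, on balance, in a single direction. Members are counted as past the threshold over all genes and also adjusted over the list alone.

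Before the data were examined, the groups, the main test, the 38 lists, the alternatives listed next and the rule for naming genes had been fixed. The rule named Csmd1, Csmd2 and Csmd3. It added the 10 higher and the 10 lower genes of largest fold change among those past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap, leaving out provisional symbols. From each list it took up to 4 members past the threshold by size, and from a list called by camera also the 2 members with the smallest p in its direction. Genes named outside this rule are said to be so. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, the replicate number as a block, sex as a covariate, sex-linked genes left out, a fit that was not robust, other thresholds, and each library left out in turn.

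Added after seeing the data were counts divided by 4, the omission of knockout libraries 2 and 3 (which hold many Ttr counts), trends on GC content and exon length removed per library (lowess span 0.3), TMM factors computed without the strongly higher genes, and 8 marker lists used in the closing section. The plan named a sex covariate without fixing its coding. The first coding split Xist at the midpoint on the log scale and took wild-type 1, 2 and 3 and knockout 2 as Xist-high. After its results were seen it was replaced by a split at 50% of the highest Xist level (wild-type 2 and 3 and knockout 2), because the Y-linked level of wild-type 1 was 80.8% of the highest. The change raised the counts from 266 higher and 73 lower genes to 796 and 408, and both codings are reported.

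The steps were tested on simulated counts for the same 19844 genes, with the means and library sizes of the real libraries and 200 changed genes. The changed genes were drawn from those with a mean above 1 CPM. Genes varied independently, with a dispersion set by expression level. The rates that follow therefore do not cover low genes or genes that vary together. In that simulation of knockout against wild type, 22.1% of 1.5-fold changes, 77.3% of 2-fold changes and 95.5% of 4-fold changes were called in the right direction. Of 132 calls, 3 fell on unchanged genes, and with no gene changed 0 genes were called. Figures were drawn with matplotlib 3.10.9. The labels do not say that the libraries came from separate embryos, so p-values measure the spread between these samples, which may be in part technical.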

Results

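Gene expression was measured by bulk RNA sequencing in the cortex of mouse embryos at embryonic day 18, in 3 wild-type and 3 Csmd3-knockout libraries. The design asks which transcripts of the late embryonic cortex differ when Csmd3 is lost. Csmd3 encodes a large membrane protein with CUB and Sushi domains, the protein modules also found in regulators of complement. Deposited totals were 60716370, 58879568 and 57531791 counts in the wild-type libraries and 68269607, 62987291 and 54244288 in the knockout libraries. The most abundant gene, Tuba1a, took 0.792% to 1.077% of them. After filtering, 19844 genes were compared.

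Csmd3 (ENSMUSG00000022311.15, chromosome 15, 47580637 to 48792063, minus strand, mm10) was lower in all 3 knockout libraries but was not absent. Its deposited counts were 992, 765 and 867 in wild type and 675, 653 and 543 in knockout, or 15 ± 1.72 and 9.98 ± 0.294 CPM (SD, n = 3). The log2 fold change was -0.59 (SE 0.13, adjusted p = 0.0233). The counts cover the whole gene and the removed part is not given in the sources used here, so reads from the remaining exons enter this value. The fall was also close to the median of the 503 lower genes (-0.58), so its size does not set Csmd3 apart. It therefore checks the genotype labels only weakly. The call was lost when wild-type library 1 (adjusted p = 0.0826) or knockout library 1 (0.0905), 2 (0.0741) or 3 (0.101) was left out, while the fold change stayed between -0.67 and -0.52. Of the CSMD family, the relatives Csmd1 (log2 fold change -0.35, SE 0.17, adjusted p = 0.265) and Csmd2 (-0.06, SE 0.10, adjusted p = 0.79) did not pass, so 1 of 3 members fell, also when adjusted over the list alone.

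The knockout samples of cortex held more transcripts of the meninges, blood vessels and macrophages and of dividing cells. They held less of transcripts for synapses and the neuronal cytoskeleton. More meningeal tissue in those samples may account for the rise of meningeal, macrophage and vascular genes, as weighed in the closing section. These list calls hold with camera's preset correlation and none holds with an estimated one (lowest adjusted p = 0.0851). In all, 1033 genes rose and 503 fell. The genes that rose had a median log2 fold change of 1.04 and took 2.03% of the counts in wild type and 3.33% in knockout, whereas those that fell had a median of -0.58. At a change of at least 2-fold, 533 genes were higher and 68 lower. All 1536 genes past the threshold had groups that did not overlap, as did 5772 of all tested genes (29.1%, where chance gives 10%). The counts moved when a library was left out: leaving out any library but wild-type 3 gave 472 to 669 higher and 137 to 227 lower genes, and leaving out wild-type 3 gave 1402 and 956. Without knockout libraries 2 and 3, which held many counts of the choroid plexus gene Ttr, far fewer genes passed. Most of the lower ones were not among the 503. That fit assumes that the single knockout library left varied like the others, and it put Csmd3 at -0.60.

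**Figure D1:**
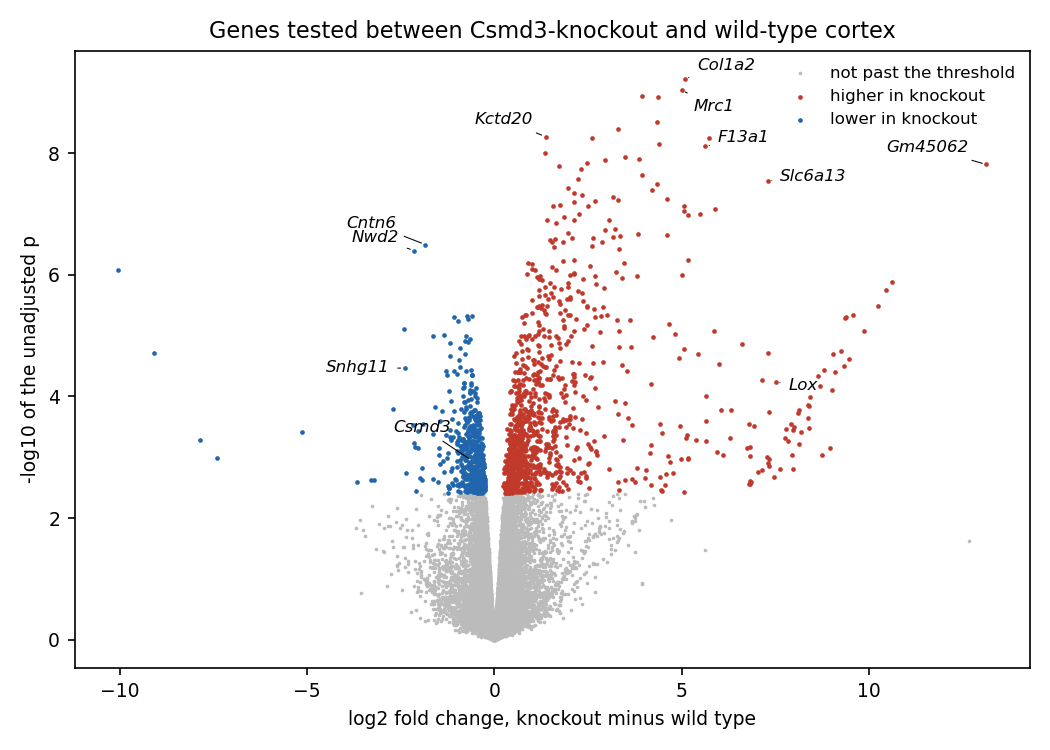
Log2 fold change (x axis, knockout minus wild type) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y axis) for the 19844 genes tested in 3 wild-type and 3 knockout libraries, each point a gene. The 1033 higher genes (red) reach far larger fold changes than most of the 503 lower genes (blue), and the fitted size of points at the far left and right depends on the constant added to counts of 0.

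The meninges, the membranes around the brain, and the mural cells of vessels gave the list with the smallest camera p. Of 25 tested markers of these cells 23 rose (all 25 when adjusted over the list alone), with a median log2 fold change of 3.07 (camera adjusted p = 1.18e-26; adjusted p = 0.0851 with an estimated correlation). Among them were the fibrillar collagen gene Col1a2, at 5.15 ± 0.884 CPM in wild type and 174 ± 24.8 CPM in knockout (log2 fold change 5.08, SE 0.17, adjusted p = 5.87e-06), the matrix genes Dcn (5.18, SE 0.32), Lum (6.06, SE 0.72) and Postn (3.95, SE 0.17), and Slc6a13, a GABA transporter of the meninges (7.30, SE 0.38). Without wild-type library 1 Lum was at 7.17, and without wild-type library 3 Slc6a13 was at 8.03. Microglia and macrophage genes rose as well: 13 of 21 were higher (15 when adjusted over the list alone). Together these genes had a median of 0.95 (camera adjusted p = 4.14e-13; adjusted p = 0.0851 with an estimated correlation). The largest changes in that list were in F13a1 (5.63, SE 0.28), the mannose receptor gene Mrc1 (5.0, SE 0.21) and Pf4 (4.83, SE 0.51; 5.91 without wild-type library 1), while Csf1r, the receptor on which microglia depend, rose by less (1.28, SE 0.13). Many of the genes named in this section overlap an annotated gene on the opposite strand, which makes their counts less certain. Besides the pairs given below, these are Lox, F13a1, Enpp2, Csf1r, Ccnd2, Pdgfra, Mfap4, Slc2a1, Notch1, Hmgcs1, Atp5l, Syt4, Grin1, Unc5c, Sv2b, Gpr17, Gabra5, Olig1, Grm7 and Nwd2, and Pdgfra and Snhg11 overlap a small RNA gene on the same strand. Of 21 endothelial genes 11 rose (15 higher and 1 lower when adjusted over the list alone), among them Cdh5, the cadherin of endothelial junctions (1.58, SE 0.11), Tek (1.17, SE 0.16), Kdr (1.04, SE 0.15) and the glucose transporter gene Slc2a1 (0.66, SE 0.08). Over the list the median was 0.66 (camera adjusted p = 9.24e-08; adjusted p = 0.251 with an estimated correlation).

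Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were also higher in knockout, unevenly between libraries. Of 11 tested, 3 rose (6 when adjusted over the list alone). The median log2 fold change was 3.30 (camera adjusted p = 6.15e-06, or 0.248 with an estimated correlation), 4.86 without wild-type library 1 and 2.58 without knockout library 3. The 3 were the water channel gene Aqp1 (4.24, SE 0.43), Enpp2 (1.94, SE 0.19) and Slc13a4 (5.94, SE 0.89; 7.84 without wild-type library 1), whose call was lost without wild-type library 3 or without any 1 of the knockout libraries (highest adjusted p = 0.0682). Ttr, the most abundant choroid plexus transcript, had 131, 2262 and 25057 deposited counts in the knockout libraries against 4, 0 and 0 in wild type and did not pass (adjusted p = 0.148). The counts of Ttr and of the markers given next are shown although the naming rule did not choose them. In knockout libraries 1, 2 and 3, Folr1 had 0, 40 and 242, Kcne2 0, 38 and 260, and Otx2 0, 30 and 87. Aqp1 was also highest in library 3 (467, 396 and 824). Slc13a4 was highest in library 1 (829, 409 and 382), and Enpp2 had 1632, 1145 and 1625. The called genes therefore did not all follow Ttr, and whether they came from choroid plexus was not tested. None of 9 tested erythroid genes passed (0 also when adjusted over the list alone; median 0.28, camera adjusted p = 0.106), and the mean level of that list was 0.55 ± 0.33 (SD, n = 3) above wild type on the log2 scale. Of 18 astrocyte genes 4 rose, also when adjusted over the list alone, among them Gja1 (3.33, SE 0.26) and Sparc (1.01, SE 0.09), both also known from meningeal or vascular cells, and the list was not called by camera (median 0.08, camera adjusted p = 0.195).

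Some genes of innate immunity were higher as well. In the complement list, to whose proteins CSMD domains are related, 7 of 23 genes rose and 1 fell (9 and 2 when adjusted over the list alone). The median of this list was 0.47 (camera adjusted p = 0.000181; adjusted p = 0.251 with an estimated correlation). C1qa, a microglial product, rose by 1.17 (SE 0.17), and Srpx2 had 0 counts in wild type and was at least 10.6-fold higher. C5ar1 had 7 deposited counts in wild type and 197 in knockout, a fold of 22.9 (95% interval 6.00 to 194), and its call was lost without wild-type library 2 or any knockout library (highest adjusted p = 0.0768); its fitted log2 value of 4.64 became 8.98 without wild-type library 1. The complement median was 0.78 without wild-type library 1, 0.74 without wild-type library 3 and 0.78 without knockout library 2. Of 23 interferon response genes 7 rose (9 when adjusted over the list alone), such as the antiviral gene Ifitm3 (1.75, SE 0.22) and the class I antigen subunit gene B2m (1.20, SE 0.14). Together these genes had a median of 1.20 (camera adjusted p = 9.24e-08; adjusted p = 0.0851 with an estimated correlation).

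**Figure D2:**
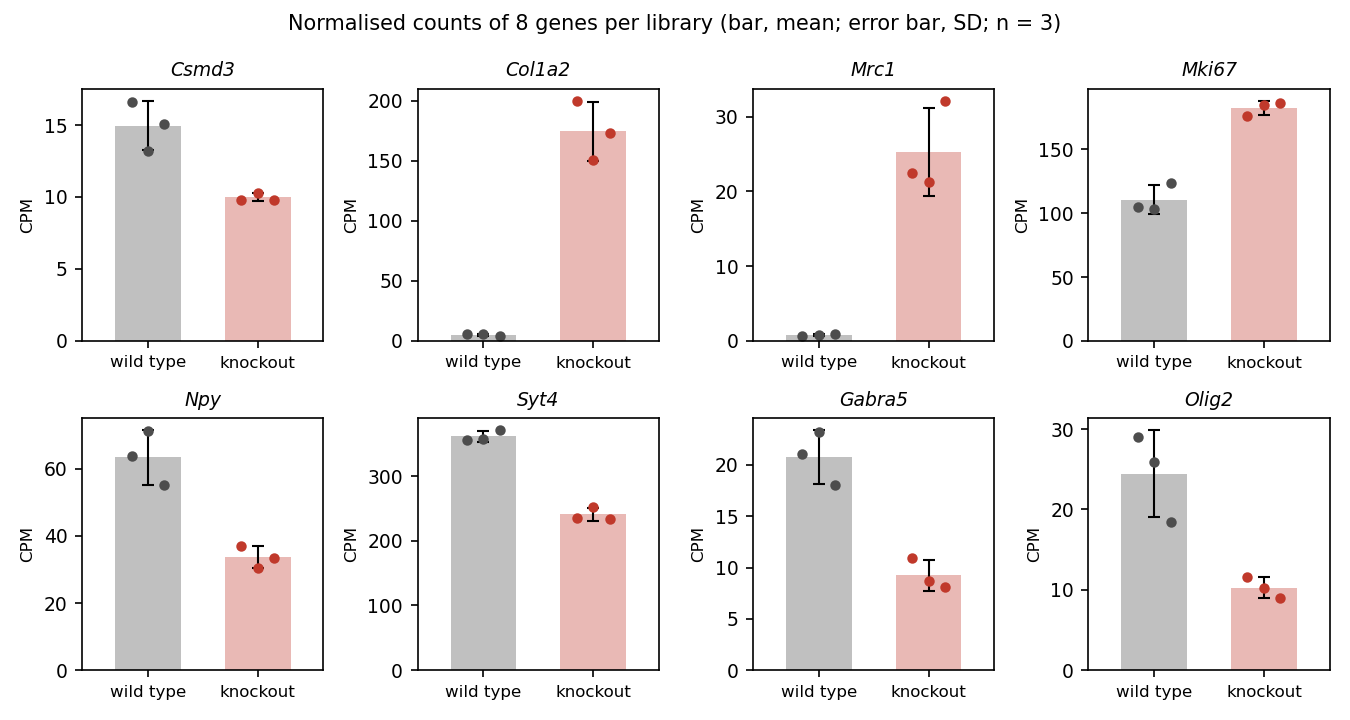
CPM (y axes, TMM-scaled, each starting at 0) of 8 genes in 3 wild-type and 3 knockout libraries, with points for libraries, bars for means and error bars for SD. Col1a2, Mrc1 and Mki67 lie higher in all 3 knockout libraries, and Csmd3, Npy, Syt4, Gabra5 and Olig2 lie lower in all 3.

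The 10 genes that rose most were drawn from those with a mean log2 CPM of at least 1. They held only 5 to 49 deposited counts over the 3 wild-type libraries, so that mean came from knockout. Among them were genes of collagen, of transport across membranes and of cell junctions. Lox, an enzyme that cross-links collagen, rose from 0.114 ± 0.103 to 21.2 ± 7.80 CPM (log2 fold change 7.51, SE 0.69, adjusted p = 0.00375), and the transporter genes Slc22a6 (7.32, SE 0.77) and Slc6a13 (7.30, SE 0.38) rose as well. With wild-type counts near 0 these values moved with single libraries: Lox was at 8.20 without wild-type library 1, Slc22a6 at 9.20 without wild-type library 2 and Slc6a13 at 8.03 without wild-type library 3. Itih2 and Osr1, given next, had fitted values of 11.19 and 11.67 without wild-type library 1. For 5 of the 10 the wild-type group held 1 to 3 fragments, and folds with 95% intervals were 215 (38.2 to 8520) for Itih2, 152 (41.8 to 1260) for the epithelial cadherin gene Cdh1, 149 (41.0 to 1240) for the transcription factor gene Osr1, 113 (38.5 to 552) for Lyve1, a marker of border macrophages and lymphatic vessels, and 112 (38.1 to 547) for the gap junction gene Gjb6. The remaining members were Col6a1 (6.94, SE 0.76) and the tight junction gene Cldn11 (6.83, SE 0.86). With libraries left out, 5 of these calls were lost although the log2 fold changes stayed large. Gjb6 (6.15 without wild-type library 1 to 11.86 without wild-type library 3) lost its call without any 1 of the knockout libraries (highest adjusted p = 0.0686) and Lyve1 (6.23 to 11.88, the latter without wild-type library 1) without knockout library 1 or 3 (0.053). Col6a1 (6.36 to 7.46) lost it without wild-type library 1 or knockout library 1 or 3 (0.0531), Cdh1 (6.24 without wild-type library 1 to 11.68 without wild-type library 2) without wild-type library 1 or knockout library 2 or 3 (0.0675), and Cldn11 (6.25 to 7.57, the latter without wild-type library 1) without any 1 library but wild-type 2 (0.0697).

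Genes of the cell cycle rose together. Of 32 tested, 21 rose (31 when adjusted over the list alone) and 0 fell, with a median log2 fold change of 0.58 (camera adjusted p = 6.49e-16; adjusted p = 0.251 with an estimated correlation). Mki67, expressed only in dividing cells, went from 111 ± 12 to 182 ± 5.61 CPM (0.72, SE 0.08, adjusted p = 0.00112), Ccnd2, the cyclin of cortical progenitors, from 302 ± 16.1 to 550 ± 44.5 CPM (0.87, SE 0.08), and the mitotic genes Hmmr (0.99, SE 0.16), Bub1 (0.81, SE 0.14) and Cenpe (0.79, SE 0.11) were higher as well. Intermediate progenitors, the dividing cells that give rise to most cortical neurons, had 4 of 12 markers higher (9 when adjusted over the list alone). Over the list the median was 0.56 (camera adjusted p = 1.53e-05; adjusted p = 0.30 with an estimated correlation). The 4 were Mfap4 (0.67, SE 0.11), Btg2 (0.61, SE 0.11), Tfap2c (0.61, SE 0.15) and the proneural factor gene Neurog2 (0.52, SE 0.10). The call of Neurog2 was lost without wild-type library 1 or 2 or knockout library 2 or 3, and that of Tfap2c without any library but wild-type 3 (highest adjusted p = 0.062 and 0.153). In radial glia, the stem cells of the cortex, 5 of 20 genes rose (7 higher and 2 lower when adjusted over the list alone), among them Notch1 (0.48, SE 0.09) and Pax6 (0.43, SE 0.08). Both calls were lost without wild-type library 1 or knockout library 1 or 3 (highest adjusted p = 0.0774 for each), and the list was not called by camera (median 0.15, camera adjusted p = 0.0628). The 44 replication-dependent histone genes had a median of 0.38 (camera adjusted p = 0.0125; adjusted p = 0.30 with an estimated correlation) with 0 members past the threshold, also when adjusted over the list alone. Hist2h2be was at 0.48 (SE 0.15, adjusted p = 0.084). Without wild-type library 1 the histone list was not called (adjusted p = 0.0543). In the same 3 knockout libraries the meningeal list lay 3.27 ± 0.18 (SD, n = 3) above wild type.

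Genes of synapses fell by smaller amounts. Of 29 genes of presynaptic vesicle release 12 fell (18 when adjusted over the list alone) and 0 rose, with a median of -0.28 (camera adjusted p = 2.39e-08; adjusted p = 0.251 with an estimated correlation). Syt4, a synaptotagmin of secretory vesicles, went from 362 ± 8.30 to 241 ± 10.1 CPM (-0.58, SE 0.06, adjusted p = 0.00066), and Sv2b fell by 0.76 on the log2 scale (SE 0.13), a call lost without knockout library 3 (adjusted p = 0.0559). Of 34 genes of the glutamatergic postsynapse 8 fell and 1 rose (9 and 2 when adjusted over the list alone). The median log2 fold change was -0.20 (camera adjusted p = 8.30e-05; adjusted p = 0.251 with an estimated correlation). The obligatory NMDA receptor subunit gene Grin1 (-0.62, SE 0.09) and Grin3a (-1.14, SE 0.18) kept their calls with any single library left out, while that of the metabotropic receptor gene Grm7 (-1.46, SE 0.26) was lost without knockout library 3 (adjusted p = 0.0577). Of 20 GABAergic synapse genes 7 fell (8 when adjusted over the list alone), such as the receptor subunit gene Gabra5, from 20.8 ± 2.59 to 9.21 ± 1.45 CPM (-1.17, SE 0.15, adjusted p = 0.00192), and the GABA transporter gene Slc6a11 (-0.93, SE 0.12). The median of this list was -0.32 (camera adjusted p = 5.97e-06; adjusted p = 0.251 with an estimated correlation). The GABAergic synapse median was -0.18 without wild-type library 1.

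Some genes of the neuronal cytoskeleton and a few of ion channels were lower. Of 37 genes of dendrites and cytoskeleton 13 fell (19 when adjusted over the list alone) and 0 rose, with a median of -0.20 (camera adjusted p = 9.18e-07; adjusted p = 0.179 with an estimated correlation). The neurofilament genes Nefl (-1.07, SE 0.16) and Nefm (-0.81, SE 0.12), which overlap each other on opposite strands, and the growth cone gene Gap43 (-0.58, SE 0.08) were lower. Voltage-gated channels had 3 of 32 genes lower (5 when adjusted over the list alone), among them the sodium channel gene Scn8a (-0.81, SE 0.13). Together these genes had a median of -0.19 (camera adjusted p = 0.000621; adjusted p = 0.411 with an estimated correlation), which was -0.12 without wild-type library 1. In these libraries the lists of meninges and of microglia and macrophages lay 3.27 ± 0.18 and 1.42 ± 0.07 (SD, n = 3) above wild type.

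Among neuron types and glia the changes were uneven. Of 14 upper-layer projection neuron genes 5 fell, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.00891; adjusted p = 0.251 with an estimated correlation), led by Rasgrf2 (-1.35, SE 0.16), and without wild-type library 3 the list was not called (adjusted p = 0.113). Deep-layer and subplate neurons had 3 of 19 genes lower (2 higher and 6 lower when adjusted over the list alone) and the list was not called by camera (median -0.16, camera adjusted p = 0.0999). Of 25 GABAergic interneuron genes 5 fell (1 higher and 9 lower when adjusted over the list alone), among them the neuropeptide gene Npy, from 63.4 ± 8.09 to 33.7 ± 3.28 CPM (-0.91, SE 0.11, adjusted p = 0.00153), and Htr3a (-0.68, SE 0.13), whose call was lost without knockout library 3 (adjusted p = 0.0642). Over the list the median was -0.32 (camera adjusted p = 0.000243; adjusted p = 0.36 with an estimated correlation). The interneuron median was -0.16 without knockout library 2. In the oligodendrocyte lineage the fate factors Olig1 (-1.40, SE 0.21) and Olig2 (-1.26, SE 0.18) fell, as did Gpr17 (-0.79, SE 0.17), whose call was lost without wild-type library 1 or 2 or knockout library 1 or 2 (highest adjusted p = 0.0843). Pdgfra, which meningeal fibroblasts express as well, rose (0.76, SE 0.11). That made 3 of 16 lower and 1 higher (4 and 1 when adjusted over the list alone). The median log2 fold change was -0.33 (camera adjusted p = 0.0143; adjusted p = 0.30 with an estimated correlation), and without wild-type library 1 the list was not called (adjusted p = 0.0516). Of 12 Cajal-Retzius genes 1 fell, also when adjusted over the list alone (median -0.21, camera adjusted p = 0.18).

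**Figure D3:**
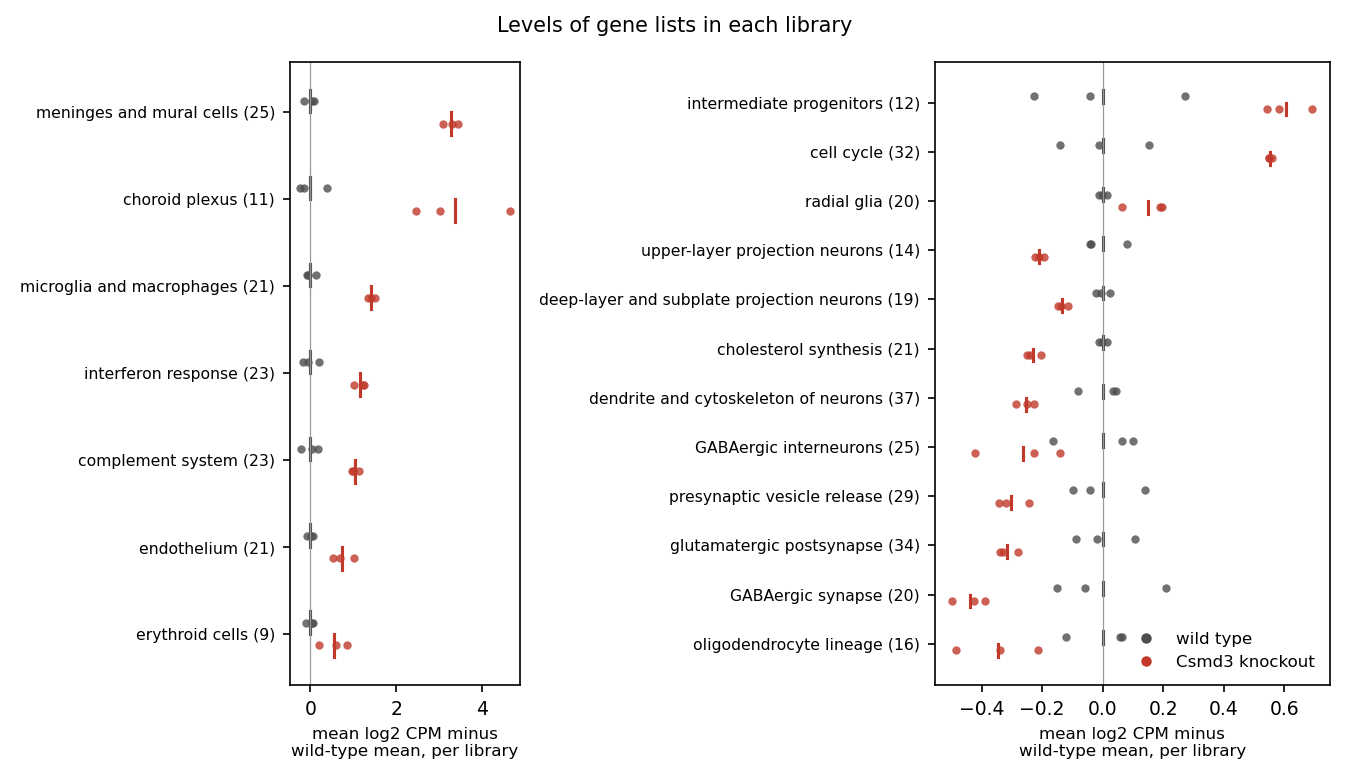
Mean log2 CPM over the genes of a list, minus the wild-type mean (x axes, log2 units, different ranges on the left and right), for 19 gene lists with their numbers of tested genes in parentheses; points are libraries and vertical bars group means, for 3 wild-type (grey) and 3 knockout libraries (red). The meningeal list lies 3.27 ± 0.18 (SD) above wild type in knockout, the cell cycle list 0.55 ± 0.01 above, and the GABAergic synapse list at -0.44 ± 0.05.

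The 10 genes that fell most among well expressed genes were led by 2 transcripts with little known protein product, Srrm4os (-2.41, SE 0.27, adjusted p = 0.000953), which lies antisense to Srrm4, and Snhg11 (-2.39, SE 0.27, adjusted p = 0.0027), a host of small nucleolar RNA. Since strand handling is not stated, the reads of Srrm4os and Srrm4 cannot be told apart with certainty, and Srrm4, outside the naming rule, had a log2 fold change of 0.57 and did not pass (adjusted p = 0.080). Nwd2 fell from 31.1 ± 5.32 to 7.08 ± 1.38 CPM (-2.13, SE 0.17, adjusted p = 0.000122) and Cntn6, a cell adhesion gene of the contactin family, from 14.4 ± 0.351 to 4.03 ± 0.553 CPM (-1.84, SE 0.15, adjusted p = 0.000103). Fam19a1 (-1.64, SE 0.19), Grm7, the calmodulin-binding protein gene Nrgn (-1.44, SE 0.29), Olig1 and Rprml (-1.35, SE 0.31) were also in the group. Of these, the calls of Nrgn and Rprml were lost without any single library but wild-type 3 (highest adjusted p = 0.0952 and 0.127).

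The lists of cholesterol synthesis, nuclear respiratory chain and ribosomal protein genes were lower by small amounts. Of 21 cholesterol synthesis genes 5 fell (7 when adjusted over the list alone), among them Hmgcs1, from 533 ± 8.14 to 432 ± 13.8 CPM (-0.30, SE 0.06, adjusted p = 0.0171), a call lost without any 1 of the knockout libraries (highest adjusted p = 0.106). The median of this list was -0.24 (camera adjusted p = 5.65e-05; adjusted p = 0.0851 with an estimated correlation). Nuclear genes of the respiratory chain had a median of -0.15 (camera adjusted p = 8.30e-05; adjusted p = 0.543 with an estimated correlation) and 1 of 52 lower (0 when adjusted over the list alone). This was Atp5l (-0.36, SE 0.08), whose call was lost without any single library but wild-type 3 (highest adjusted p = 0.102). Cytosolic ribosomal protein genes had a median of -0.11 (camera adjusted p = 8.30e-05; adjusted p = 0.657 with an estimated correlation) with 0 of 82 past the threshold, also when adjusted over the list alone. Both medians moved with the wild-type libraries: without wild-type library 2 they were -0.09 and -0.04, and the ribosomal list was then not called (adjusted p = 0.054). Without wild-type library 1 the ribosomal median was -0.17. The 13 mitochondrially encoded genes had a median of -0.04, a mean of 0.03 and 0 members past the threshold, also when adjusted over the list alone (camera adjusted p = 0.808).

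Stress, signalling and regional lists were not called by camera, although fry called 3 of them: thalamus and hypothalamus (fry adjusted p = 0.00502), heat shock (0.0215) and immediate early genes (0.0454). Immediate early genes had 4 of 23 higher (8 when adjusted over the list alone; median 0.07, camera adjusted p = 0.106), among them Atf3 and Dusp6. Their calls were lost without wild-type library 1 or any knockout library, and that of Atf3 also without wild-type library 2 (highest adjusted p = 0.0966 and 0.0791). Heat shock genes had 1 of 17 higher (camera adjusted p = 0.075), hypoxia genes 1 of 25 (0.157), and genes of the unfolded protein and amino acid response 2 of 24 higher and 1 lower (0.201), each with the same counts when adjusted over the list alone. Slc7a11, a cystine transporter gene, rose by 3.06 (SE 0.22) and the asparagine synthetase gene Asns was lower (-0.46, SE 0.11), a call lost without any single library but wild-type 3 (highest adjusted p = 0.139). Axon guidance genes had 2 of 43 higher and 1 lower (2 and 4 when adjusted over the list alone; median 0.00, mean -0.03, camera adjusted p = 0.45), with Unc5c at -0.66 (SE 0.11). Of 40 autism risk genes 1 fell, also when adjusted over the list alone (median 0.04, camera adjusted p = 0.869). Markers of neighbouring regions were scattered. The striatum had 3 of 18 higher and 1 lower (3 and 3 when adjusted over the list alone; camera adjusted p = 0.676), and hippocampus and cortical hem had 1 of 14 higher and 2 lower (2 and 2; 0.869; median -0.10, mean 0.00). Of 11 genes of thalamus and hypothalamus 2 were higher (2 and 0; 0.0628; median 0.44), these being Zic1 (1.27, SE 0.12) and Zic4 (3.33, SE 0.27), which overlap on opposite strands and are also meningeal genes. Of 28 tested neighbours of Csmd3 on chromosome 15, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.841).

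Sex-linked transcripts did not separate the genotypes. Xist, made from the inactive X chromosome of females, was at 181, 1320 and 2010 CPM in wild-type libraries 1, 2 and 3 and at 56.6, 1960 and 11.4 CPM in the knockout libraries, and the sum of 4 Y-linked genes was at 151, 32.2 and 0.0174 CPM and at 186, 38.7 and 179 CPM. None of 5 sex-linked genes passed, also when adjusted over the list alone (camera adjusted p = 0.433). Of the 37 lists, camera called 20, 9 higher and 11 lower. Fry called 20, of which 15 were also called by camera. It did not call the lists of GABAergic interneurons (adjusted p = 0.0867), the oligodendrocyte lineage (0.0529), voltage-gated channels (0.107), the respiratory chain (0.196) and ribosomal proteins (0.305), which camera called. Besides the 3 lists named above, fry alone called radial glia (0.0241) and deep-layer and subplate neurons (0.0118). With an estimated correlation camera called 0 of the 37.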

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

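The sex covariate as coded without wild-type library 1 among the Xist-high libraries, counts divided by 4, the omission of knockout libraries 2 and 3, the removal of GC and length trends and the TMM factors without higher genes were tests chosen only after the results were seen. Against 1033 higher and 503 lower genes, RLE and upper-quartile scaling, limma-voom, both filters on low counts, sex-linked genes left out, the fit that was not robust, the sex covariate in this later coding (796 and 408), counts divided by 4, GC and length trends removed and TMM without higher genes gave 796 to 1116 higher and 394 to 679 lower genes. The lower genes rose to 921 with DESeq2, which called 1032 of the 1033 and all 503, and to 918 at an adjusted p under 0.1; requiring at least a 2-fold change left 533 and 68. The replicate block gave 686 higher and 255 lower genes and Csmd3 at -0.58 (adjusted p = 0.0664; adjusted p from 0.000840 to 0.380 over its alternatives) and changed no call of a list; same-numbered libraries did not deviate together (correlations 0.028, -0.003 and 0.002), so the numbers are not taken as pairs. The first coding of the sex covariate, with wild-type library 1 among the Xist-high, gave 266 and 73, with Csmd3 at -0.54 (adjusted p = 0.279), and without knockout libraries 2 and 3 the counts were 262 and 43, with Csmd3 at -0.60 (adjusted p = 0.380); in both, genotype rests on few knockout libraries. Leaving out single libraries gave 472 to 1402 higher and 137 to 956 lower genes, and Csmd3 from -0.67 to -0.52 and Csmd2 from -0.13 to 0.039. Csmd2 changed sign near 0, at 0.039 without wild-type library 1 and 0.02 without knockout libraries 2 and 3; the cause was not tested. Of the 125 named genes past the threshold, 60 stayed past it with each library left out, 40 of 68 higher and 20 of 57 lower ones. Lists called numbered 18 to 23 with RLE and upper-quartile scaling, limma-voom, both filters on low counts, the replicate block, both codings of the sex covariate, sex-linked genes left out, counts divided by 4, and single libraries or knockout libraries 2 and 3 left out. They numbered 20 with fry and 0 with an estimated correlation.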

Other observations

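Apart from the count over other splits of the libraries, the tests in this part, those on GC content and gene length and on developmental stage included, were chosen only after the first results had been seen. The marker lists were written and the genes named here were chosen after that too. Standard errors of differences between medians, and intervals of medians, are over genes and do not measure spread between libraries. The tests used for meningeal tissue, for dilution and for RNA of both sexes replaced first choices whose values had been seen. Border macrophages, which live in the meninges and around vessels, had 11 of 13 tested markers higher, with a fitted median of 5.63, or 2.90 with genes at 0 in wild type set at their bound. Stab1 (2.13, SE 0.14) had the highest level among those that rose, at 11.7 CPM in wild type and 51.1 in knockout. Parenchymal microglia, the macrophages inside the brain, had 7 of 14 higher with a median of 0.67, and the microglial receptor gene P2ry12 was at 0.22 (SE 0.21, adjusted p = 0.608). Arachnoid and dural fibroblasts had 14 of 18 higher with a median of 3.0 (16 when adjusted over the list alone), among them the prostaglandin synthase gene Ptgds (4.42, SE 0.52) and Tbx18 (4.35, SE 0.21). Of 20 neuronal genes that rise late in gestation 12 were lower with a median of -0.53, such as Ptk2b (-0.96, SE 0.11), Atp1b1 (-0.72, SE 0.08) and Arpp21 (-0.71, SE 0.08). Of 20 cortical neuron transcription factor genes 0 passed in the edgeR test (2 higher and 2 lower when adjusted over the list alone), with a median of 0.04, and Neurod2 and Neurod6 were at 0.02 (SE 0.06) and 0.17 (SE 0.09). That list leaves out Cux2 (-0.39), Pou3f1 (-0.38) and Lmo4 (-0.53), which were lower. Their calls were lost without any 1 of the knockout libraries, without knockout library 3, and without knockout library 1 or 2, in that order (highest adjusted p = 0.0755, 0.063 and 0.0525). Of 14 late astrocyte genes 1 was lower, Cspg5 (-0.60, SE 0.08; median -0.08). Of 16 neural-only progenitor genes 2 were higher, Pax6 and Neurog2 (7 higher and 1 lower when adjusted over the list alone; median 0.19). These lists share members with other lists, fixed or added: 4, 7, 4, 0, 8, 12 and 12 genes in the order named.

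Some large differences lay outside any list, apart from that of Igf2, which is a member of the meninges and mural cell list. Grb10, an adaptor of insulin signalling, was at 68.1, 61.9 and 68.6 CPM in wild type and 178, 164 and 167 in knockout (log2 fold change 1.35, SE 0.07, adjusted p = 1.65e-05), and the imprinted genes H19 (2.62, SE 0.17) and Igf2 (2.47, SE 0.18) rose as well. Kctd20 stood at 70.1, 63.4 and 68 CPM in wild type and 170, 174 and 179 in knockout (1.37, SE 0.07, adjusted p = 1.22e-05). Gm45062 (chromosome 6, 8259450 to 8597480, plus strand) had 0 counts in all wild-type libraries and 1277, 893 and 1283 in knockout, while Glcci1, which it overlaps on the same strand, fell (-1.29, SE 0.16, adjusted p = 0.00293). Reads of overlapping genes can be assigned to either, and the sum of both was 62.0 ± 14.6 CPM in wild type and 44.1 ± 4.52 in knockout (SD, n = 3).

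The first pattern is the rise of meningeal, macrophage and vascular genes in knockout. A lower share of neural RNA would raise every other cell type alike, but the meningeal median exceeded the erythroid median by 2.79 (SE 0.61), which argues against it. More meningeal tissue in the knockout samples may account for the pattern: among genes in no fixed list and not named by the rule, the median of 8 border macrophage genes exceeded that of 7 parenchymal microglia genes by 2.30 (SE 0.35), with genes at 0 in wild type at their bound. These lists were written once border macrophage genes such as Mrc1 had been seen to rise, which weakens the test. Whether such tissue came from dissection or from a thicker or more adherent meninx in these embryos was not tested, and an effect of genotype on these cells stays open.

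The second pattern is the fall of neuronal genes and the rise of proliferation genes. Dilution by added tissue would lower all neuronal genes alike and may account for part of the fall. The median of 120 genes of 4 neuronal function lists was -0.25 and that of 33 genes of the upper-layer and deep-layer lists -0.15. This difference of -0.10 (SE 0.10) is too uncertain to argue against dilution. The 20 cortical neuron transcription factor genes had a median of 0.04, and their difference from the function lists had an SE of 0.06. For the genes covered, that argues against dilution as the whole cause. However, that list was written after the data were seen and leaves out the lower genes Cux2, Pou3f1 and Lmo4. Dividing cells of added tissue may not be the whole cause, since neural-only progenitor genes had a median of 0.19 (bootstrap interval over genes 0.07 to 0.43). However, 12 of these 16 genes are also in other lists. Camera gave this list an adjusted p of 0.0139 with the preset correlation and 0.119 with an estimated one. GC or length trends are argued against because 98.5% of 66 called genes kept their calls with those trends removed. A younger stage of the knockout embryos may contribute: late-rising neuronal genes had a median of -0.53 (interval -0.74 to -0.22), but late-rising astrocyte genes had only -0.08, so stage cannot be told apart from an effect of genotype on maturation, which the design confounds with it. A genotype effect stays open as a hypothesis.

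The third pattern is the presence of Xist and Y-linked transcripts in the same libraries, in wild-type 2 and knockout 2 above all. Index hopping between libraries would leave Y-linked counts in each of them, but wild-type library 3 held 0.00932% of the highest library's level, which argues against it. RNA of both sexes in a library, for example from pooled littermates or carried over between samples, stays open. The share of Ddx3y in the Y-linked sum had a largest to smallest ratio of 1.24 over the 5 libraries with Y-linked counts, but male RNA from any route would give that, so it decides nothing. No biological explanation was tested, and sex of embryos stays open.

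Of the 10 ways to split the 6 libraries into 3 and 3, 1, the split by genotype, gave as many as 1536 genes past the threshold, and the highest of the others gave 5. With 10 splits the share cannot be under 0.1, so this design is too small for such a test to pass 0.05.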
